A study of Rattus norvegicus with 10 samples.

How the data were processed

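Gene expression was measured in testes of postnatal day 6 pups with 10 one-colour Agilent arrays for the rat, 5 from sires with a C code and 5 from sires with a T code. Per the labels' protocols, RNA was purified on columns with DNase digestion, and 100 ng were amplified and labelled with Cy3. The deposited scanner files hold spot intensities: per the file headers, they came from Agilent Feature Extraction 10.7.3.1 (10.7 in the submitters' processing notes), which subtracts the background and corrects trends across the array, and they were not scaled between arrays. A further table holds the authors' processed values on a log2 scale for 21220 probes. Set against the scanner values of the same arrays, centred on the median of each probe, its columns correlated at 0.9978 to 0.9987 with slopes near 1, so they are log2 values centred per probe, with higher values for more signal. How they were scaled between arrays was not determined. The column medians were 0.0288, 1e-04, -0.0166, 0.0202 and -0.0089 for C replicates 1 to 5 and 0.0032, 0.0037, -0.0026, -0.0169 and -0.0023 for T replicates 1 to 5. The filter behind its choice of probes stays unknown, and it served only as an alternative source of values.

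Each array had 62976 spots, of which 4259 were controls and were left out. The scanner's processed signal was converted to log2, and the 75th percentile of each array over its 58717 other spots was subtracted. Spots with an outlier flag of the scanner software (494 to 745 per array) were set missing, and 0 were saturated. Spots of a probe were averaged, and a probe was kept if at least 5 of the 10 arrays had it well above background. This left 21892 of 30367 probes (72.1%). Values of 2 arrays correlated at 0.9899 to 0.9966 over these probes, so no array was a copy of another. Transcript accessions of the array were matched without version to a RefSeq gene table of the GRCr8 assembly, which gave a symbol to 17998 probes and left 12369 without one. The tested probes named 11561 genes, of which 1941 had more than 1 tested probe. The array was designed on the rn4 build per the file headers of 5 arrays, so no coordinates are given. For genes with several probes, the probe with the highest mean over all arrays stood for the gene in tests of lists, and named genes with probes that go different ways are marked as such.

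Differences between the groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, T minus C, two-sided), with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. The 2 groups were compared without a covariate, since no label states a test. Before the data were examined, 32 gene lists for cell types and pathways of the testis and its surroundings were written down, together with the rule for the genes named in the text, the tests and the processing alternatives. Of their 928 entries, 922 matched a gene, and 30 lists had at least 5 measured genes, while 4 of the lymphocyte and mast cell markers and 0 of the sex chromosome genes were measured. Lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry, and the mean of each list per array was compared by an exact permutation test over all splits into 5 and 5. Shifts of lists are mean log2 differences of their genes minus that of all other genes. The separation of the groups and the spread within them were tested by exact permutation over all such splits.

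The rule for named genes took the genes past the threshold, then genes with a fold change of at least 1.5 and no overlap between the groups, then up to 3 members with the smallest p of each list described in detail, and a fixed panel of 23 genes. As 0 genes passed, the first part named none, and 1 gene that the rule names is not reported here. The 15 lists described in detail were picked after their results were seen. The tests of genes and lists were checked on simulated data with the spread of these arrays, in which a list shifted by 0.1 was called with the preset correlation (adjusted p = 0.00351) and by fry but not with an estimated correlation (adjusted p = 0.0777). A list shifted by 0.2 was called by all 3, and there the preset correlation also called 1 list that had not been shifted. Genes were drawn independently in these data, with 1 draw per shift, while the correlation estimated in the measured lists reached 0.808. The check therefore cannot show how the tests of lists behave with correlated genes. Slides were read from the file headers and used as a block and separately. The alternatives tried were the background correction, the scaling, the filter on dim probes, flagged spots, the variance model, weights of arrays, thresholds, slide and sire codes as terms, the choice of probe, the set test, the authors' values and leaving out each array. Normexp on the mean spot signal was planned but not run, since the files used here give the median spot signal, which took its place. It was run with an offset of 50 units added to every signal, which by itself shrinks log2 differences of dim probes.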

Results

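Total RNA from testes of male rats on postnatal day 6 was hybridised to 10 one-colour arrays, 1 array for each of 10 sire codes. The pups came from Brown Norway fathers and Sprague Dawley mothers, and the fathers had received either saline or BEP for 9 weeks, followed by 9 weeks of recovery. BEP is the usual abbreviation of a chemotherapy of bleomycin, etoposide and cisplatin given for testicular cancer, although the labels do not spell out the drugs. The sire codes carry the letter C on 5 arrays and the letter T on 5, and C is read here as the saline fathers and T as the BEP fathers, an inference that no label states. How many pups contributed to an array is not given in the sources used here. The 75th percentile of the signal ran from 1525 units on C replicate 1 to 2686 on C replicate 3, with a mean of 2201 ± 462 (SD) in the C group and 2236 ± 265 in the T group (exact permutation p = 0.897, two-sided). Between 70.5% and 74.8% of the probes were well above background on an array, and the number of arrays limits the precision of every value. The arrays lay on 2 slides: slide 1 held 3 C and 2 T arrays, and slide 2 held 2 C and 3 T arrays.

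The first comparison asked which genes differ in the testes of pups according to the treatment of their fathers. No single gene passed the threshold. On 9 probes the difference was at least 1.5-fold and all T arrays lay on one side of all C arrays. Of these, 5 had a gene symbol that was not a provisional number, and only those are described here. Clcn1, the chloride channel of the skeletal muscle membrane, was higher in the T group (log2 difference 0.73 ± 0.21, SE, 5 arrays per group). It was well above background on 1 of the C arrays and on all 5 T arrays, so the size of this difference rests on values near the background. Wdr19, a component of the intraflagellar transport machinery of cilia, was 1.73-fold higher in the C group (log2 difference -0.79 ± 0.16), and Nfic, a transcription factor of the nuclear factor I family, was 1.64-fold higher there (-0.71 ± 0.14). Sytl4, which acts in the docking of secretory granules, and Arhgap39 were 1.56-fold and 1.53-fold higher in the C group (-0.64 ± 0.15 and -0.61 ± 0.13). A second probe gave 0.12 for Sytl4 and 0.055 for Arhgap39, and the first Sytl4 probe was well above background on only 3 T arrays. The sizes depended on the processing. With normexp background correction the differences were 0.178 for Clcn1, -0.383 for Wdr19, -0.156 for Sytl4 and -0.214 for Arhgap39. The offset of 50 units used there shrinks differences of dim probes by itself. These smaller values therefore cannot tell whether the differences depend on the background correction. Over all alternatives the differences ran from 0.178 to 1.076 for Clcn1, -1.12 to -0.383 for Wdr19, -0.785 to -0.404 for Nfic, -0.723 to -0.156 for Sytl4 and -0.686 to -0.214 for Arhgap39.

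**Figure D1:**
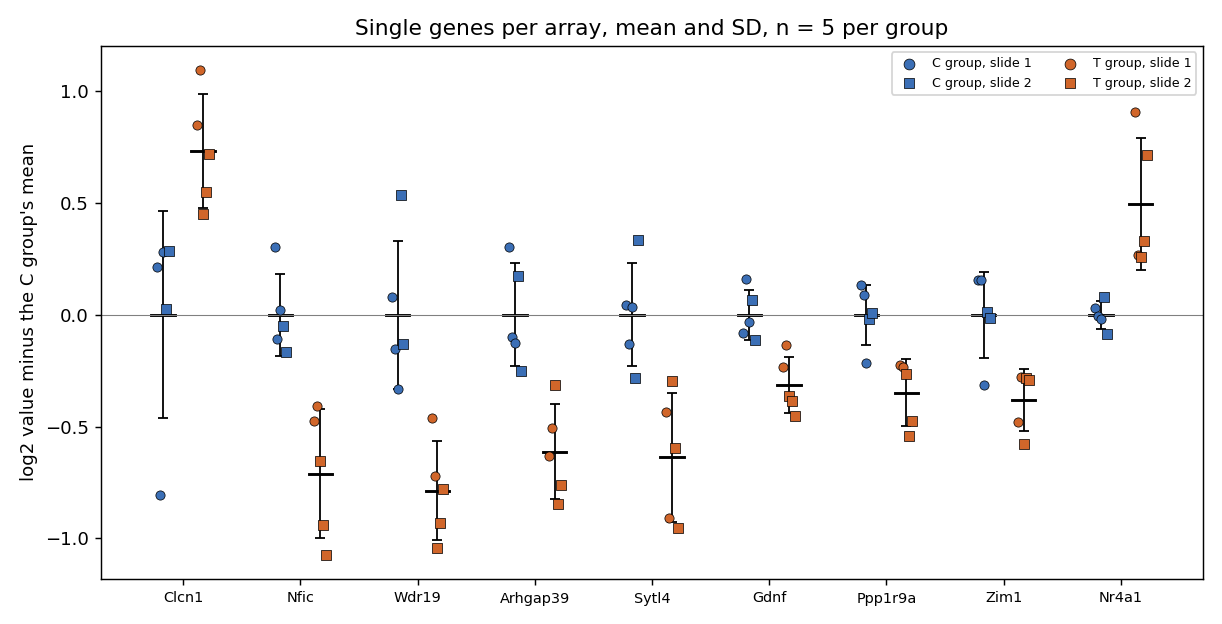
Log2 value of 9 genes on each array, minus the mean of the C group, for the C group (blue) and the T group (orange) on slide 1 (circles) and slide 2 (squares); black lines give the mean and the SD of 5 arrays. All T arrays lie above all C arrays for Clcn1 and Nr4a1 and below them for Nfic, Wdr19, Arhgap39, Sytl4, Gdnf and Ppp1r9a (for Zim1, C replicate 3 lies among the T arrays), and no difference passed the adjusted threshold over all probes.

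Of 21892 probes tested with limma, 0 had a Benjamini-Hochberg adjusted p under 0.05, and the lowest adjusted p was 0.9985. At an unadjusted p under 0.05 there were 869 probes (3.97%; 1095 would be expected by chance), 349 of them higher and 520 lower in the T group. This excess of lower probes was not stable. Most settings kept its direction, among them slide as a block (455 higher and 561 lower) and quantile normalization (386 and 617). It turned within slide 1 (391 higher and 325 lower), without C replicate 1 (382 and 350) and with the sire numbers as a block (372 and 325). With 1 probe per gene there were 257 and 271, and without C replicate 3 there were 285 and 773. The groups did not overlap on 158 of 21870 probes (0.72%), where chance gives 0.79%, and 42 of the 158 were higher and 116 lower in the T group. With slide as a block the counts were 0 adjusted and 1016 unadjusted. Within slide 1 they were 0 and 716, and within slide 2 they were 0 and 888. An equal-variance test per probe without moderation gave 0 adjusted and 898 unadjusted. Moderation with a trend and robust estimates gave 0 and 821, and weighting the arrays gave 0 and 976. The 95% confidence interval of the difference reached 0.221 on the log2 scale to either side at the median (1.17-fold), and it excluded a 2-fold difference in either direction for 97.4% of the probes and a 1.5-fold difference for 86.8%. In simulated data with 5 arrays per group and the spread of these arrays, 56.5% of 200 probes changed 1.5-fold were recovered among 21870 probes. Of 200 probes changed 2-fold, 89.5% were recovered, and of 200 probes changed by 0.322 log2 units 0 were recovered.

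The second comparison asked whether genes of a cell type or pathway moved together. Most germ cell genes of the lists stood higher in the T group, with no single one past the threshold. Of 26 measured genes of gonocytes and spermatogonia, the germ cells of the newborn testis, 19 were higher and 7 lower. Among them were Piwil2, which binds small RNAs that silence transposons (0.25 ± 0.096), and Tex101, a germ cell surface glycoprotein (0.24 ± 0.077). Tdrd1, a tudor protein of the same silencing pathway, was lower (-0.24 ± 0.088). The score of this list, the mean deviation of its genes on an array, was -0.042 ± 0.025 (SD) in the C group and 0.042 ± 0.076 in the T group, and 4 of the 5 T arrays lay above every C array, with T replicate 5 at -0.081. Of 14 genes of meiosis and spermiogenesis, 10 were higher and 4 lower. The smallest p-value was that of Ldhc, the lactate dehydrogenase of germ cells (0.40 ± 0.13). Sycp1, a protein of the synaptonemal complex (0.53 ± 0.22), and Meiob, a factor of meiotic recombination (0.40 ± 0.17), followed. Sycp1 was well above background on 2 C and 4 T arrays. With normexp it stood at 0.108, where the offset of 50 units shrinks differences of dim probes. None of the genes of either list passed a threshold adjusted over the list alone (lowest adjusted p = 0.204 and 0.161).

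Both germ cell lists passed limma's camera test with a preset inter-gene correlation of 0.01 (5 arrays per group), the gonocyte list with a mean shift of 0.087 against all other genes (adjusted p = 0.0156) and the meiosis list with 0.14 (adjusted p = 0.0212). With an estimated correlation neither did (adjusted p = 0.604 for both). The estimates were low, at 0.06 and 0.021, so the loss of these calls does not point to strong correlation among the genes. By an exact permutation test of the list scores the p-values were 0.0397 and 0.0159 before and 0.397 for both after adjustment over the lists. The gonocyte shift was 0.085 with slide as a block (adjusted p = 0.00459), 0.088 within slide 1 (adjusted p = 0.0408) and 0.081 within slide 2 (adjusted p = 0.0506). For the meiosis list the values were 0.13 with the block (adjusted p = 0.031), 0.13 within slide 1 (adjusted p = 0.0823) and 0.13 within slide 2 (adjusted p = 0.0932). The gonocyte call ended without T replicate 4 (shift 0.060, adjusted p = 0.0539), and the meiosis call without C replicate 1, T replicate 4 or T replicate 5 (shifts of 0.12, 0.12 and 0.14, with adjusted p = 0.0596, 0.0539 and 0.0646). With the sire numbers as a block both calls ended (shift 0.083, adjusted p = 0.103, and shift 0.059, adjusted p = 0.469). The meiosis call also ended with the authors' values (0.115, adjusted p = 0.0809) and with probes well above background on all 10 arrays (0.094, adjusted p = 0.0767). Over all alternatives the adjusted p ran from 5.88e-05 to 0.604 for the gonocyte list and from 0.00731 to 0.604 for the meiosis list.

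**Figure D2:**
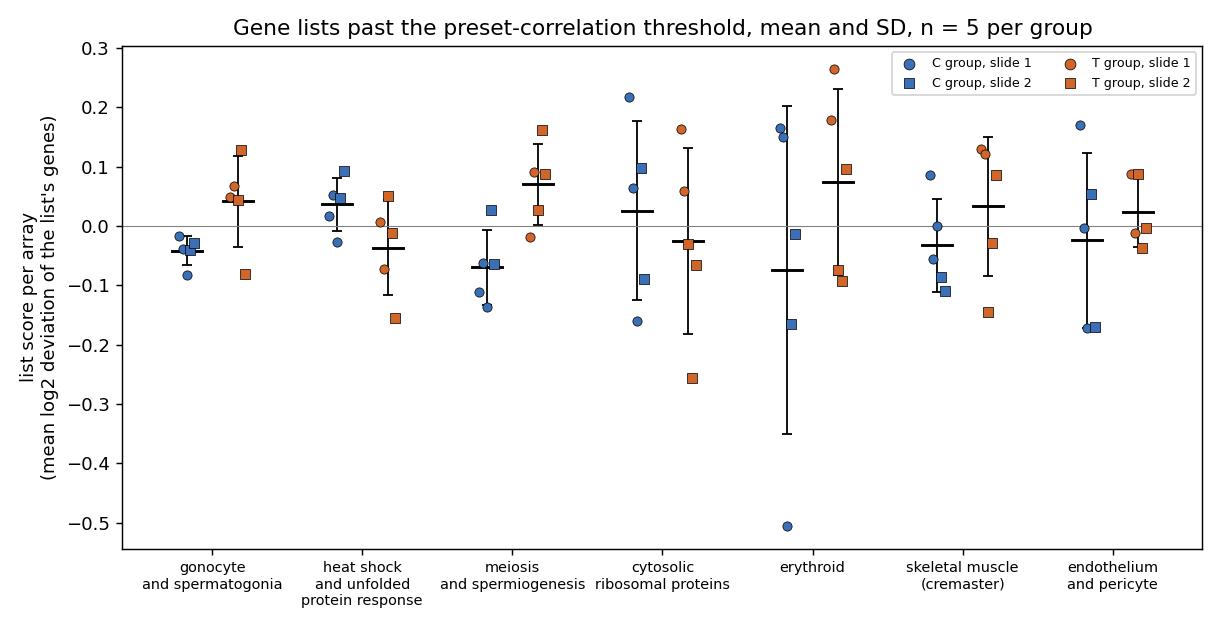
Score of each of the 7 gene lists that passed the test with the preset correlation, as the mean log2 deviation of the genes of the list on an array, for the C group (blue) and the T group (orange) on slide 1 (circles) and slide 2 (squares); black lines give the mean and the SD of 5 arrays. The groups overlap in every list, and C replicate 3 lies at -0.51 in the erythroid list.

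Chaperones and genes of the unfolded protein response were lower in the T group, in 21 of 24 measured members. The smallest p-values were those of Herpud1, a membrane protein of the endoplasmic reticulum that takes part in protein degradation (-0.16 ± 0.062), Hspa5, the main chaperone of the endoplasmic reticulum (-0.18 ± 0.084), and Pdia4, a disulfide isomerase (-0.18 ± 0.092). The list shifted by -0.070 with the preset correlation (camera, adjusted p = 0.0156), but with an estimated correlation the adjusted p was 0.667 and the exact permutation p of the scores was 0.119. The shift was -0.079 with slide as a block (adjusted p = 0.00459), -0.063 within slide 1 (adjusted p = 0.0704) and -0.095 within slide 2 (adjusted p = 0.0173). Without C replicate 5 it was -0.048 (adjusted p = 0.105) and without T replicate 5 -0.042 (adjusted p = 0.124). Over all alternatives the adjusted p ran from 0.00167 to 0.667.

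Transcripts of cytosolic ribosomal proteins were lower by a small amount in the T group in 70 of 73 members, among them Rpl38 (-0.18 ± 0.11), Rpl35a (-0.17 ± 0.16) and Rpl18 (-0.12 ± 0.11). The shift of -0.049 passed with the preset correlation (camera, adjusted p = 0.0363), while the correlation estimated among these genes was 0.808 and gave an adjusted p = 0.778. The exact permutation p was 0.595. The direction differed between the slides: the shift was 0.056 within slide 1 (adjusted p = 0.046) and -0.11 within slide 2 (adjusted p = 3.59e-06), and it was -0.026 with slide as a block (adjusted p = 0.31). The p-values within slides use the preset correlation, far below the estimate of 0.808, and do not measure the spread between testes. On each slide the scores of the groups overlapped. Without T replicate 4 the shift was 0.005 (adjusted p = 0.689). The call also ended without C replicates 1, 2 or 4 or T replicate 5, with shifts of -0.015, -0.039, -0.037 and -0.040 and adjusted p between 0.103 and 0.747. It ended as well with quantile normalization (-0.011, adjusted p = 0.515), the number in the sire code as a term (-0.015, adjusted p = 0.514), the mean of the probes of a gene (-0.041, adjusted p = 0.0662) and the sire numbers as a block (0.033, adjusted p = 0.126). Over all alternatives the adjusted p ran from 3.59e-06 to 0.928.

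Most markers of cells other than those of the seminiferous tubule stood higher in the T group in 3 lists. Of 10 erythroid genes 8 were higher, including Hbb-b1, a beta globin (0.28 ± 0.17), Alas2, the first enzyme of erythroid haem synthesis (0.28 ± 0.15), and Slc4a1, the anion exchanger of the red cell membrane (0.26 ± 0.17). Of 14 genes of skeletal muscle 10 were higher, among them Actn2, an actinin of the sarcomere (0.33 ± 0.10), Myl1, a myosin light chain (0.28 ± 0.13, well above background on 3 arrays of each group), and Myh8, the perinatal myosin heavy chain (0.24 ± 0.11). Of 14 genes of endothelium and pericytes 11 were higher, including Pecam1, an adhesion molecule of endothelial junctions (0.21 ± 0.082), and Flt1 and Kdr, receptors of vascular endothelial growth factor (0.18 ± 0.078 and 0.15 ± 0.082). The shifts were 0.15 for the erythroid list (camera, adjusted p = 0.0391), 0.069 for skeletal muscle (adjusted p = 0.0402) and 0.052 for endothelium (adjusted p = 0.0469). With an estimated correlation none passed (adjusted p = 0.735, 0.604 and 0.735), and the exact permutation p-values were 0.333, 0.318 and 0.532.

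With slide as a block the shifts were 0.18 for the erythroid list (adjusted p = 0.018), 0.092 for skeletal muscle (adjusted p = 0.0187) and 0.056 for endothelium (adjusted p = 0.0659). Within slide 1 they were 0.27 (adjusted p = 0.0408), 0.10 (adjusted p = 0.0775) and 0.024 (adjusted p = 0.605), and within slide 2 they were 0.081 (adjusted p = 0.0932), 0.083 (adjusted p = 0.0932) and 0.088 (adjusted p = 0.0173). The erythroid shift was 0.057 without C replicate 3 (adjusted p = 0.333), whose score of -0.51 was the lowest. Without that array Hbb-b1, Alas2 and Slc4a1 stood at 0.136, 0.133 and 0.127. The erythroid call also ended without C replicates 4 or 5 or T replicates 1, 2 or 5 (shifts from 0.11 to 0.18, adjusted p from 0.0595 to 0.187). The skeletal muscle call ended without C replicates 2, 4 or 5 or T replicates 1, 2, 4 or 5 (shifts from 0.050 to 0.080, adjusted p from 0.0539 to 0.131). The endothelial call ended without C replicates 3 or 5 or T replicates 1, 3, 4 or 5 (shifts from 0.023 to 0.063, adjusted p from 0.0539 to 0.311). Both of these calls also ended with normexp, with the authors' values, without a filter on dim probes and with probes well above background on all 10 arrays. The shifts there ran from 0.038 to 0.075 for skeletal muscle (adjusted p from 0.0581 to 0.12) and from 0.01 to 0.054 for endothelium (adjusted p from 0.0528 to 0.136). The skeletal muscle call ended with the sire numbers as a block too (0.112, adjusted p = 0.0623). Over all alternatives the adjusted p ran from 0.00256 to 0.809 for the erythroid and the endothelial lists and from 0.00812 to 0.604 for skeletal muscle.

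In all, 7 of 30 lists passed with the preset correlation, 5 higher and 2 lower in the T group, and 0 passed with an estimated correlation (lowest adjusted p = 0.604). By fry, which asks whether a list moves on balance in one direction, 0 passed (lowest adjusted p = 0.428). The exact permutation test gave a lowest adjusted p = 0.397, but its splits allow no single list an adjusted p under 0.238, and 5 lists at the smallest p would be needed to pass. With slide as a block 5 passed with the preset correlation and 0 with an estimated one. The adjusted p of the 23 lists that did not pass ran from 0.128 to 0.774.

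The lists of Sertoli and Leydig cells did not pass the threshold. Of 31 Sertoli cell genes, those of the cells that nurse the germ line, 12 were higher and 19 lower in the T group (camera, adjusted p = 0.248). The smallest p-value was that of Gdnf, the growth factor that maintains spermatogonial stem cells, at -0.31 ± 0.080, with all T arrays below all C arrays. Its adjusted p with limma, adjusted over the list alone, was 0.079. Kitlg, the ligand of the Kit receptor of germ cells, stood at -0.24 ± 0.10, with its 3 probes between -0.41 and -0.11, and Ptgds, a prostaglandin D synthase, at 0.54 ± 0.23 (0.125 within slide 1 and 1.063 within slide 2). The 20 genes of Leydig cells, the source of testosterone, were split into 10 higher and 10 lower (camera, adjusted p = 0.774), with Insl3, a peptide hormone of testicular descent, at 0.35 ± 0.18, Hsd11b1, a glucocorticoid-converting enzyme, at 0.19 ± 0.085 and Prlr, the prolactin receptor, at -0.22 ± 0.10.

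Lists of the response to DNA damage did not pass either. Of 21 targets of p53, 15 were higher and 6 lower (camera, adjusted p = 0.248), with Tp53inp1, a regulator of apoptosis, at 0.17 ± 0.081, Sesn2, a stress-induced sestrin, at -0.14 ± 0.11 and Zmat3, a zinc finger protein, at -0.086 ± 0.053. The DNA repair list had 13 genes higher and 17 lower (camera, adjusted p = 0.248), with Brca1, of homologous recombination, at -0.27 ± 0.11 and Lig4, the ligase of end joining, at -0.17 ± 0.083. Its score was lower in the T group, at -0.018 ± 0.024 against 0.018 ± 0.020 (SD), with an exact permutation p = 0.0317 before and 0.397 after adjustment over the lists.

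Of 25 measured genes of DNA methylation and chromatin modification, 7 were higher and 18 lower (camera, adjusted p = 0.248), among them Kdm4a, a histone demethylase (-0.16 ± 0.066), Trim28, a corepressor that keeps imprints and silences retroelements (-0.13 ± 0.082), and Ezh2, a histone methyltransferase (-0.095 ± 0.065). Imprinted genes were split into 12 higher and 12 lower (camera, adjusted p = 0.363). Adjusted over the list alone, 2 of the 24 passed with limma at an adjusted p = 0.044, against 0 over all probes tested. One was Ppp1r9a, which encodes the actin-binding neurabin, at -0.35 ± 0.090, with all T arrays below all C arrays. The other was Zim1, a zinc finger gene, at -0.38 ± 0.10, whose second probe stood at 0.14, so its direction depends on the probe. This adjustment was made for each list separately and does not allow for the number of lists. With slide as a block the unadjusted limma p rose from 0.0029 to 0.0042 for Ppp1r9a and from 0.00365 to 0.00547 for Zim1. Whether they pass over the list with that block was not tested. Nnat, which encodes neuronatin, stood at -0.19 ± 0.079.

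Among 22 immediate early genes 13 were higher and 9 lower (camera, adjusted p = 0.248). Nr4a1, an orphan nuclear receptor induced rapidly by many stimuli, was 1.41-fold higher in the T group (0.50 ± 0.13) with all T arrays above all C arrays, and its p adjusted over the list alone was 0.056 with limma over all probes and 0.048 when 1 probe per gene was fitted. Neither value allows for the number of lists. Junb and Nr4a3, also rapidly induced transcription factors, stood at 0.31 ± 0.16 and 0.30 ± 0.16. Without C replicate 2 the list passed (shift 0.11, adjusted p = 0.0413). The proliferation list had 16 genes higher and 20 lower (camera, adjusted p = 0.586), with the G1 cyclins Ccnd2 at -0.29 ± 0.093 and Ccne2 at -0.38 ± 0.13 and the mitotic cyclin Ccnb1 at 0.091 ± 0.061.

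A panel of 23 genes of testis function and of the paternal exposure was reported whatever its result, and 18 of them were measured, with 11 higher and 7 lower in the T group and 0 at an unadjusted p under 0.05 (limma). Differences ran from -0.28 ± 0.15 for Amh, the Sertoli cell hormone that removes the Müllerian ducts, to 0.35 for Insl3. Genes of steroid synthesis stood at 0.22 ± 0.13 (Hsd3b1), 0.16 ± 0.19 (Cyp11a1), 0.068 ± 0.27 (Cyp17a1) and -0.052 ± 0.24 (Star). The inhibin subunit Inha and the follicle-stimulating hormone receptor Fshr stood at -0.046 ± 0.093 and 0.003 ± 0.095. The germ cell genes Ddx4, Dazl, Kit and Gfra1 stood at 0.24 ± 0.15, 0.15 ± 0.077, 0.051 ± 0.11 and -0.006 ± 0.088. Ddx4 was 0.035 within slide 1 and 0.354 within slide 2. The imprinted pair H19 and Igf2, of fetal growth, stood at 0.052 ± 0.11 and -0.12 ± 0.12. The de novo methyltransferase Dnmt3a stood at -0.073 ± 0.064 and its cofactor Dnmt3l at 0.20 ± 0.41. The direction of Dnmt3l rests on T replicate 5 (-0.188 without it, and 0.047 with slide as a block). The p53 targets Cdkn1a and Mdm2 stood at -0.12 ± 0.20 and 0.036 ± 0.060, with a second Cdkn1a probe at 0.050. Leaving out single arrays also turned the direction of Inha, Fshr, Star, Cyp17a1, Kit, Gfra1 and H19. The confidence interval reached beyond a 2-fold difference for 1 of the 18, Dnmt3l. No tested probe was named for Sox9, Lhcgr, Dnmt1, Dnmt3b or Mki67. On the 2 slides taken separately, 11 of the 18 had the same direction and 7 opposite directions.

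The third comparison asked whether the testes of one group resemble each other more than those of the other group. They did not: the mean distance between arrays of different groups was 51.5 log2 units and that within groups 52.8, a difference of -1.38 (exact permutation p = 0.738, one-sided, 93 of 126 splits as large). Splits within slides gave p = 0.67, and the values were -2.14 within slide 1 (exact p = 0.9) and -1.73 within slide 2 (exact p = 0.8). The slides, in contrast, were separated by 11.8 (exact p = 0.0079, the smallest that 126 splits can give), and the first principal component, with 35.7% of the variance, placed all arrays of slide 1 below 0 and all arrays of slide 2 above it.

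**Figure D3:**
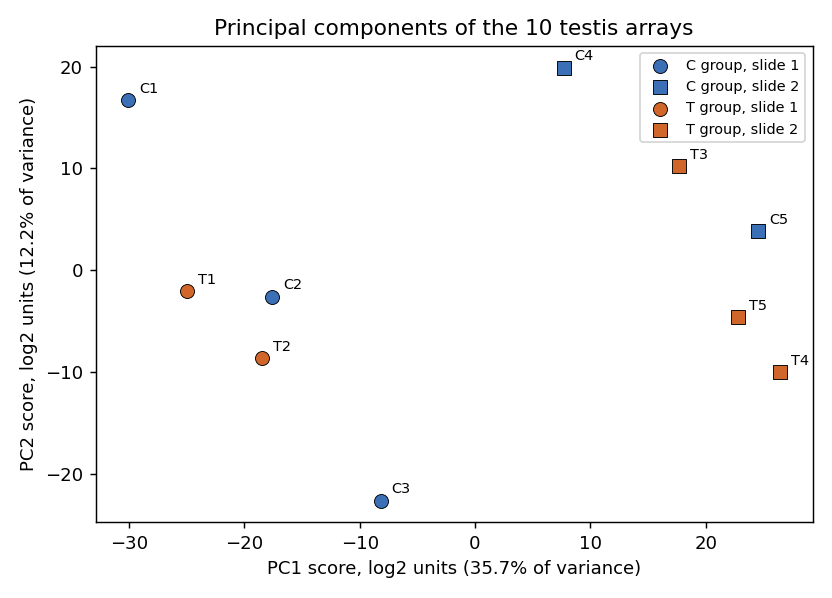
Scores of the 10 arrays on the first component (35.7% of the variance) and the second component (12.2%), in log2 units, for the C group (blue) and the T group (orange) on slide 1 (circles) and slide 2 (squares). The first component divides the arrays by slide, from -30.1 for C replicate 1 to 26.4 for T replicate 4, and not by group.

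The fourth comparison asked whether pups of one group vary more among themselves. The variance over the T arrays was 0.953 of that over the C arrays at the median probe (log2 ratio -0.070, exact permutation p = 0.881, two-sided). Within slides, where the unequal numbers of arrays move the ratio itself, the log2 ratio was -1.64 on slide 1 (exact p = 0.3) and 0.44 on slide 2 (exact p = 0.7), and the 10 splits of a slide allow no p under 0.1.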

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

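The tests on the other spots of the probes in the corner of T replicate 4 and the test on Leydig cell genes for Hsd3b3 were chosen only after the result was seen, as were the tests within single slides and without that corner. Dixon's test for a value far from the rest of its group marked 4 of 134 sets of 5 arrays for named genes and 0 of 62 for lists, where chance marks about 1 in 20. Hsd3b3 and Iqcm were tested because of their outlying values, so their marks are not set against that rate.

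Hsd3b3, an enzyme of steroid metabolism of the 3-beta-hydroxysteroid dehydrogenase family that was picked out after its values were seen, lay at -8.81 on C replicate 5, not well above background there, against -0.96 to -0.19 on the other C arrays (ratio of gap to range 0.911) and -1.13 to 0.001 over the other 9 arrays. Both spots of its probe were low, by -7.76 and -8.78, although they lie 120 rows and 44 columns apart, and the 63 spots around them had a median deviation of -0.021, which argues against a local defect of the array. The 20 measured Leydig cell genes had a median deviation of -0.004 on that array (range -0.84 to 0.75), which argues against fewer Leydig cells, and the related Hsd3b1 and Hsd3b5 lay at 4.30 and -0.20, inside the range of the other arrays. A sequence variant under the probe or a loss of this transcript in that testis may account for the value, and neither was tested, nor was any difference between litters.

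T replicate 4 had a dim corner, where 37 of 247 spots lay at least 2 log2 units below the other arrays (median -4.57), among them spots for Dusp22, a phosphatase, and Wrnip1, a partner of the Werner helicase. The 117 spots of the same probes elsewhere on that array had a median deviation of 0.105 and 0 of them were low, which argues against lower expression of the genes with such spots in that testis and is consistent with a local defect of the array. For 8 of the 37 probes there was no other spot, so this says nothing about them. Counted over tested probes only, no other array had such spots in that corner, and 23 spots elsewhere on T replicate 4 lay as low. The scanner software had marked 16 of the 37. Without the corner 0 genes and 7 lists passed, as with it. What damaged the spots stays open.

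The arrays divided by slide far more than by group. With the group as a term, limma called 2143 probes between the slides, 253 higher and 1890 lower on slide 2. A number in the sire code, which is 2 on 3 arrays, all of them on slide 2, was tested as another source: with both as terms, 782 probes were called for slide and 0 for the number, and the number alone called 0, which argues against the number as the source of the division. A smaller part of the number is not excluded, since both numbers occur only on slide 2. There the arrays with number 2 lay at 22.81 to 26.44 on the first component, against 7.70 and 17.73 for the others. Handling of the arrays of a slide together, or litters that happened to share a slide, may account for the division, and these were not told apart by any test. Both groups lie on both slides, so slide could be used as a block in the comparison of the groups.

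Other divisions of the 10 arrays into 5 and 5 were tried, in 100 drawn of 126 with the real one included. As 0 genes passed in the real division, 100 of the 100 reach that count by definition, and this says nothing about chance. Another division gave 2521 at most, the one that follows the slides, and 10 of the 100 had any call. For the next 2 counts, chance is not excluded. At least as many probes had an unadjusted p under 0.05 in 36 of the 100 (869 in the real division, 6148 at most in another), and at least as many lists passed with the preset correlation in 12 of the 100 (7 in the real division, 9 at most in another, 4 at the median). Among the 78 divisions with the same balance over the slides as the real one, 14 and 12 did. The counts of genes near the slide division point to a structure of the samples that follows the slides. With slide as a block 0 genes and 5 lists passed.

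Kitlg lay at 1.26 on T replicate 5 and between 1.68 and 1.83 on the other T arrays (ratio 0.734). Inha lay at 4.23 on T replicate 4 and between 4.53 and 4.64 on the others (ratio 0.726). Dnmt3l lay at -3.42 on T replicate 5 and between -5.60 and -5.15 on the others (ratio 0.796). Clcn1 lay at -7.88 on C replicate 2 and between -7.05 and -6.79 on the other C arrays (ratio 0.766), with only C replicate 5 of these well above background. Iqcm, a gene with an IQ motif that was picked out after its values were seen, lay at -0.44 on T replicate 3 by one probe and between -3.71 and -3.08 on the other T arrays (ratio 0.807), at 0.45 by another and between -3.12 and -2.54 on the others (ratio 0.836), while the remaining tested probe had no such gap.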

How the results depend on the processing

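Chosen only after the data were seen were the settings with slide 1 or slide 2 alone, normexp on the median signal, the dim corner left out, splits within slides, and an estimated correlation with slide as a block. Over 1800 refits of the 67 named genes, 1759 kept their direction and side of the threshold and 41 turned in direction (12 genes), with the lowest adjusted p at 0.759. Of the 41, 37 fell on the 18 panel genes and 4 on the 49 others, which were picked for their p or separation on these arrays, so their stability is partly built in. Sizes moved more: 172 refits shrank by over 1.5 times or turned and 76 grew by over 1.5 times, in 62 of the genes. Of the 67 genes, 23 shrank or turned so with normexp, 33 with the replicate block and 30 within slide 1. The offset of 50 units in normexp shrinks differences of dim probes by itself, so its count does not measure the background correction alone. Over 810 refits of lists, 678 stayed, 76 lost a call, 13 gained one and 43 turned. A list turned where its mean shift changed sign, and its test could still point the same way. The count of 0 genes held in every setting with an adjusted threshold, with the lowest adjusted p at 0.17 (slide 1 alone), and 37 probes passed at an unadjusted p under 0.05 with a 1.5-fold change. The 7 lists became 4 with the authors' values, 4 with probes well above background on all 10 arrays, 0 with an estimated correlation with or without slide as a block, and 0 with fry. The filter for all 10 arrays leaves fewer probes, and the authors' values change the source and the probes together. The cause of these changes was not tested beyond the choice itself. Signal over background limits probes near the floor, and 5778 probes were well above it on none of the arrays.

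The replicate block takes the sire numbers 2, 4 and 6, shared by a C and a T array, over 6 arrays. The deviations of same-numbered arrays from their group means correlated at -0.512 for number 2, whose arrays lie on different slides. They correlated at 0.282 and 0.194 for numbers 4 and 6, whose arrays share a slide. Pairs on one slide averaged 0.259 (0.066 to 0.405) against -0.239 across slides (-0.512 to -0.041). The same-numbered pairs were not the closest of either kind, so these correlations show no sign that the numbers pair the arrays. Slide was not taken out of the deviations, and so few pairs cannot exclude a pairing. With the block 0 genes and 3 lists passed. Values that turned there were Rpl35a 0.041, Sesn2 0.008, Inha 0.061, Star 0.245, Kit -0.053, Dnmt3l -0.599 and Cdkn1a 0.21, and the lists peritubular myoid 0.017, nerve and glia -0.08, proliferation 0.019, mitochondrial respiratory chain 0.029 and ribosomal proteins 0.033. The test of the peritubular myoid list still pointed down there. This fit has fewer samples.

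Within slide 1 the values that turned were Rpl35a 0.08, Ccnb1 -0.017, Inha 0.059, Star 0.163, Cyp17a1 -0.214, Kit -0.185, Gfra1 0.081 and Cdkn1a 0.094, and the lists Sertoli cell 0.023, Leydig cell -0.023, macrophage -0.047, p53 targets -0.013, apoptosis regulators -0.003, immediate early genes -0.003, cholesterol synthesis -0.073, mitochondrial respiratory chain 0.042, ribosomal proteins 0.056 and extracellular matrix -0.032. Within slide 2 they were Fshr -0.036, and the lists peritubular myoid 0.032, epididymis and rete -0.083, adipocyte 0.071, nerve and glia -0.028, DNA methylation 0.007, proliferation 0.017, glycolysis 0.013, interferon response -0.018 and tight and gap junctions -0.135. The test still pointed up for p53 targets within slide 1 and down for peritubular myoid within slide 2. These fits have fewer samples.

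Single settings turned Gfra1 to 0.002 (median in place of the 75th percentile) and 0.005 (authors' values), Fshr to -0.028 and Star to 0.097 (array weights), Cyp17a1 to -0.002 (slide as a block), and the log2 ratio of the spread to 0.007 (quantile normalization). The nerve and glia list turned to -0.002 with normexp, -0.038 without a filter on dim probes, -0.017 with probes well above background on all 10 arrays and -0.009 with the mean of the probes of a gene. Tight and gap junctions turned to -0.005 with normexp and -0.001 with probes well above background on all 10 arrays, and cholesterol synthesis to -0.009 without a filter. In the fit reported these values lay between -0.070 and 0.068, and the cause was not tested. The test of nerve and glia still pointed up with normexp and with the mean of the probes of a gene. That of tight and gap junctions pointed down in the fit reported and in both settings where its shift turned. The extracellular matrix list gained a call with quantile normalization (0.056, adjusted p = 0.0315), and within slide 2 calls were gained by it (0.084), the Sertoli cell (-0.077), macrophage (0.143), immediate early (0.143), cholesterol synthesis (0.114) and mitochondrial (-0.057) lists, with adjusted p from 0.00177 to 0.0322. Tight and gap junctions passed there too (-0.135, adjusted p = 0.0322). Their mean shift had turned, but the test pointed down as in the fit reported. Within slide 1 cholesterol synthesis (-0.073, adjusted p = 0.0466), mitochondrial (0.042, adjusted p = 0.046) and ribosomal protein (0.056, adjusted p = 0.046) lists passed in the direction opposite to slide 2. These calls within slides use the preset correlation and do not measure the spread between testes. Whether the slides differ was not tested.

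Leaving out each array in turn gave 0 genes each time and 1 to 7 lists (3 without C replicate 5, 2 without T replicate 4 and 1 without T replicate 5). The separation ran from -2.33 to -0.067 and the spread ratio from -0.293 to 0.314, with 0.314 without C replicate 1 and 0.028 without C replicate 5. Values that turned without some array ran from -0.084 to 0.027 for Inha, -0.045 to 0.058 for Fshr, -0.184 to 0.087 for Star, -0.082 to 0.237 for Cyp17a1, -0.01 to 0.145 for Kit, -0.06 to 0.044 for Gfra1, -0.188 to 0.38 for Dnmt3l and -0.009 to 0.11 for H19. For lists they ran from -0.009 to 0.043 (Leydig cell), -0.261 to 0.004 (adipocyte), -0.018 to 0.045 (nerve and glia), -0.022 to 0.044 (cholesterol synthesis), -0.091 to 0.005 (ribosomal proteins) and -0.018 to 0.09 (tight and gap junctions).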

Other observations

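No test of a hypothesis is added in this part, and the searches for variable lists and for genes with separate levels were chosen only after the data were seen. Genes of the extracellular matrix were the nearest to the threshold among the lists not described above: 21 of 26 were higher in the T group (mean 0.038, camera adjusted p = 0.128). This list passed without C replicate 1, C replicate 4 or T replicate 2 (adjusted p = 0.00342, 0.0291 and 0.0317, shifts from 0.060 to 0.064). Contractile genes of peritubular myoid cells, which surround the tubules, were lower in 10 of 13 (mean -0.046, adjusted p = 0.196), and genes of the mitochondrial respiratory chain in 34 of 46 (mean -0.031, adjusted p = 0.248), a list that passed without T replicate 1 or T replicate 2 (shifts of -0.055 and -0.044, adjusted p = 0.00731 and 0.0367). Antioxidant and glutathione genes (21 of 34 lower), glycolysis and hypoxia genes (17 of 25 lower) and hormone and growth factor genes (27 of 43 lower) each had an adjusted p of 0.248. Macrophage genes (12 of 21 higher, adjusted p = 0.337), retinoic acid genes (11 of 19 higher, adjusted p = 0.363), interferon-responsive genes (16 of 27 higher, adjusted p = 0.581) and cholesterol synthesis genes (13 of 24 higher, adjusted p = 0.774) did not pass either. For tight and gap junctions the signs differ: the mean was 0.030, the median -0.038 and the test pointed down (adjusted p = 0.292). The apoptosis regulators (mean 0.022, median -0.020, adjusted p = 0.586) and the nerve and glia list (mean 0.015, median -0.012, adjusted p = 0.774) had a mean and a median of opposite sign, with the test pointing up. Adipocyte genes (7 of 9 lower, adjusted p = 0.248) and genes of epididymis, rete and mesothelium (9 of 12 higher, adjusted p = 0.363) complete the lists tested. The 4 measured lymphocyte and mast cell genes, too few to test, had a mean of -0.12 and a median of 0.088.

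Testes of the same group differed more in some lists than the groups did. The adipocyte list had the widest spread over the 10 arrays (SD 0.327), from -0.35 on C replicate 3 to 0.82 on C replicate 1, a 2.24-fold range, and the erythroid list ran from -0.51 on C replicate 3 to 0.27 on T replicate 2 (1.71-fold). The epididymis, rete and mesothelium list ran from -0.32 on C replicate 3 to 0.30 on C replicate 4. The DNA repair list and the apoptosis regulators varied least, each with an SD of 0.028.

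Single genes chosen after their values were seen varied more widely. Cdh16, a cadherin of kidney-type epithelium, ran from -8.99 on T replicate 5 to -3.66 on T replicate 4, and Cldn3, a claudin of tight junctions, from -7.12 on C replicate 2 to -2.05 on T replicate 3. Dlx5, a homeobox gene, ran from -8.94 on C replicate 2 to -4.24 on T replicate 3, and Sst, which encodes somatostatin, from -8.91 on C replicate 2 to -3.82 on T replicate 1. The lowest value of each of these 4 genes was not well above background, so the ranges are not exact. For all 4 genes C replicate 4, T replicate 1 and T replicate 3 were among the 4 highest arrays.

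On 13 of 21870 probes the 10 arrays fell into 2 levels with at least 2 arrays each. The gap between the levels was at least 1.5 log2 units and at least 2 times the range of the arrays within either level, so probes with wider levels or with a single array apart are not counted. None of the 13 followed the groups, and 4 followed the slides. For the 6 of them with several spots, each spot gave the same division. The 5 probes with a symbol belong to 4 genes. RT1-CE10, a class I gene of the major histocompatibility complex, averaged -3.33 on 7 arrays and was not well above background on C replicate 2 and T replicates 3 and 5. Cdh8, a cadherin, averaged -4.70 on 6 arrays and was not well above background on C replicates 2, 4 and 5 and T replicate 3. Fabp12, a fatty acid binding protein, averaged -2.90 on 8 arrays and -5.77 on C replicate 4 and T replicate 1. Fam111a, a protease gene, was high on C replicate 4 and T replicates 1 and 5 by both of its probes, -0.55 against -3.04 and -0.79 against -2.82.

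A pair of probes without a symbol was well above background on all 5 C arrays and on 0 T arrays. They were 1.87-fold and 1.78-fold higher in the C group (limma, adjusted p = 0.9985 for both). These are means of the C arrays over those of the T arrays, with each T array set to no less than its lowest signal well above background. The values are estimates and not lower limits, and on the first of these probes the groups overlapped.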
